A study of Arabidopsis thaliana with 4 samples.

How the data were processed

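Total RNA from rosette leaves and roots of Arabidopsis thaliana was measured on 4 Agilent 1-colour microarrays labelled with Cy3. The groups were nrt1.5 leaves, Col-0 leaves, nrt1.5 roots and Col-0 roots, with 1 array each. Col-0 is the wild type, and nrt1.5 is the nrt1.5-5 insertion mutant of NRT1.5 (NPF7.3, AT1G32450), a nitrate transporter that loads the xylem for transport from root to shoot. Per the labels, plants grew hydroponically and not under sterile conditions, with 10 h of light and 14 h of darkness, and were harvested at 9 weeks after 6 weeks of nitrogen limitation at 0.1 mM ammonium nitrate. The leaf samples held leaf number 13 and younger leaves.

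The deposited scanner files hold intensity values per spot, made by the authors with Agilent Feature Extraction. Per the file headers the software version was 11.0.1.1, while the submitters' processing notes give 10.1. The processed signal had been background-subtracted and detrended within each array by that software and not scaled between arrays. The mean signal and local background of each spot are intensity values without correction, per the file headers. Other deposited columns are flags of that software, in units listed as other: well above background, saturated, non-uniform and population outlier. A deposited table of the authors' processed values holds intensity values for 35334 probes on a linear scale. In that table the 4 columns have the same sorted values, with a median of 66.44 in each, so it was quantile normalized and not log-transformed or centred. Its log2 values correlate with the scanner values at r between 0.98 and 0.99, so it runs in the same direction. Of 21990 probes well above background on every array, 1134 (5.16%) lay more than 1 log2 unit from the scanner value on all arrays, and 96.65% of those share their gene with another probe, against 31.81% of the others. How these probes were combined is not stated in the labels.

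Each array carried 45220 spots, of which 1417 were controls. Control spots and spots marked as outliers, between 4 and 17 per array, were left out. The main scale was log2 of the processed signal minus the array's 75th percentile over all other spots, and spots of 1 probe were averaged on the log2 scale. The 43603 probes were matched to loci through RefSeq accessions, gene names, locus codes or synonyms. A single locus was found for 36051 probes, several loci for 496 and none for 7056; the last pair of classes was kept out of the gene table. Probe places come from the file headers' TAIR10 annotation, and gene names from the TAIR10.1 reference table. Of 25989 loci with a probe, 7672 had several, and the probe with the highest mean level among those well above background on at least 3 arrays stood for the gene. A gene counted as measured in a comparison when its probe was well above background on at least 1 of the 2 arrays.

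Genotypes were compared within each organ as the log2 difference, nrt1.5 minus Col-0. A gene is written as having risen or fallen when the difference was 2-fold or more and the brighter array was well above background. Where the other array was not well above background, the change is a lower bound against the higher of that array's signal and its lowest signal among probes well above background, between -7.12 and -6.69 on the log2 scale, and is written as at least N-fold. With 1 array per group there is no replicate check: no p-value, standard error or spread between plants can be given. The number of arrays limits the precision. The 50 probes with 5 spots each had a median SD of 0.08 to 0.09 log2 units within an array, which covers the array only, not plants, extraction or labelling. Different probes of 1 gene spread over a median range of 0.29 log2 units in the leaf comparison (6195 genes) and 0.34 in the root comparison (6443 genes), with 90th percentiles of 0.75 and 0.86. Of called genes with several such probes, 97 of 343 in leaves and 100 of 147 in roots had a probe below 2-fold, and 20 and 34 had a probe of the opposite sign.

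For 38 gene lists the number of risen and fallen members and the median log2 difference were computed. The median's percentile among 10000 random lists of the same size, matched on mean level in 20 bins, describes these arrays and is not a p-value. A list is said to stand apart at a percentile of 2.5 or less or 97.5 or more. Lists with fewer than 3 measured members got no median. The lists, the thresholds, the main scale, the named-gene rule and most alternatives were fixed before the data were examined. The rule named NRT1.5, HAK5, SKOR, NRT1.8, NRT2.1, NRT2.4, NRT2.5, SAG12, NIA1 and NIA2 whatever their values. In each organ it named the 12 largest rises and 12 largest falls among genes well above background on both arrays that pass 2-fold under normexp, quantile, median and loess scaling too. It added the 4 largest lower bounds per direction, up to 2 risen and 2 fallen members per list, and 5 genes per class that changed in the same or in opposite directions in both organs. It gave 190 genes. Genes named outside this rule are said to be chosen after their values were seen.

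Alternatives were normexp background correction with an offset of 50 on the mean and background signals, quantile normalization, median centring, the 75th percentile over probes detected on every array, loess with a span of 0.3, the authors' table, no filter on dim probes, a filter on both arrays, the mean of all probes of a gene, and a 3-fold threshold. Scaling to the spike-in controls was added after the data were seen. Slide 1 carried both leaf arrays and slide 2 both root arrays, so organ and slide cannot be told apart. Within each slide the genotypes lay at the same pair of array positions on both slides, so genotype and position coincide. Correlations between leaf and root differences are across genes, which are not independent replicates, and got no p-value.

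The calls were tested on simulated data with 200 changed genes per comparison and noise of 0.2 log2 units. Changes of 1.5 log2 units were recovered for 99 of 100 genes in the leaf setting and 98 of 100 in the root setting, changes of 2 log2 units for 100 of 100 in each, and 0 unchanged genes were called. Of 200 simulated unchanged lists, 2.5% stood apart in each setting. The noise had the same size for every gene, and background flags were copied from the Col-0 array. The simulation therefore checks the calculation and does not give the rate of false calls on these arrays. The work used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.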

Results

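The data are 4 genome-wide expression arrays of Arabidopsis plants kept on limited nitrogen for 6 weeks, 1 for each genotype in each organ. The 75th percentile of the processed signal was 435.19 for nrt1.5 leaves, 530.67 for Col-0 leaves, 530.91 for nrt1.5 roots and 606.32 for Col-0 roots. Between 73.07% and 77.93% of the spots on an array were well above background, and 0 spots were saturated. The scanner software rated the Col-0 root array for evaluation, with a spike-in coefficient of variation of 8.45% against 3.83% to 3.98% on the others. There are no replicates, so every value below compares single arrays.

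The disrupted gene gave lower signal in the mutant in both organs. The probe of NRT1.5 (AT1G32450), at chromosome 1, 11715346 to 11715405, fell by 5.05 on the log2 scale in roots, from 5.55 in Col-0 to 0.49 in nrt1.5, which is 33.2-fold lower. In leaves it fell by 2.89, from 0.87 to -2.02, or 7.43-fold lower. All 4 levels were well above background. The labels do not give the place of the insertion, so whether this probe lies beyond it is unknown.

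The leaf comparison asks how the shoot differs in plants whose root-to-shoot nitrate transporter is disrupted. With 1 leaf array per genotype, an effect of the disruption cannot be told apart from any other difference between the samples. Jasmonate and defence genes rose, and CYP94B3 (AT3G48520), which hydroxylates jasmonoyl-isoleucine, was 180-fold higher in nrt1.5 leaves. TAT3 (AT2G24850), a tyrosine aminotransferase, was 333-fold higher, and RNS1 (AT2G02990), a ribonuclease of the phosphate starvation list, 320-fold. Of 20 anthocyanin and flavonoid genes 12 rose, including CHS (AT5G13930), chalcone synthase, at 7.55-fold. SAG12 (AT5G45890), a cysteine protease used as a marker of leaf senescence, went the other way and was 35.3-fold lower in nrt1.5. Of 20678 genes measured in leaves, 1356 rose and 805 fell.

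Further large rises in leaves were JRG21 (126-fold), the calcium-binding protein gene CML41 (82.0-fold), the pirin gene PRN (80.5-fold), WRKY38 (76.1-fold), a thionin gene (AT1G66100, 62.0-fold), the terpene synthase gene TPS04 (58.0-fold), the defensin gene PDF1.2A (56.9-fold) and NATA1 (55.1-fold). The other probes of WRKY38 differed by 2.31 to 6.96 log2 units and that of AT1G66100 by 3.16. An uncharacterized gene, AT5G05250, rose 121-fold. Among genes well above background in nrt1.5 leaves only, an oxygenase-like gene (AT2G38240) was at least 363-fold higher. ENDO2, which encodes an endonuclease, was at least 119.9-fold higher, MDHAR, a monodehydroascorbate reductase gene, at least 107.7-fold and the methyltransferase gene BSMT1 at least 67.0-fold.

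After SAG12, and leaving NRT1.5 itself aside, the largest falls in leaves among genes well above background on both arrays that also passed 2-fold under normexp, quantile, median and loess scaling were MRD1 (19.6-fold lower), a heavy-metal-associated domain gene (AT4G08570, 8.82-fold), FER1 (8.19-fold), the ferritin gene, the xyloglucan-modifying gene XTH31 (7.17-fold), AT1G76800, which resembles vacuolar iron transporters (6.45-fold), the gibberellin-inactivating gene ATGA2OX1 (6.33-fold) and BGLU47 (5.11-fold). The other FER1 probes ranged from -3.17 to 0.65 log2 units. AT3G20340, AT4G29905 and AT1G29600 fell by 2.32 to 3.04 log2 units. Among genes well above background in Col-0 leaves only, SMB (SOMBRERO, a root cap transcription factor) was at least 17.3-fold lower, AT5G55110 at least 18.7-fold, AT3G10460 at least 16.5-fold and AT4G35165 at least 12.5-fold. With normexp background correction SMB, AT3G10460 and AT4G35165 were no longer 2-fold lower, at -0.53, -0.40 and -0.94 log2 units.

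Of 30 jasmonate synthesis and response genes, 26 rose in leaves and 0 fell, with a median of 2.33 log2 units at percentile 100. Beside CYP94B3 and PDF1.2A these included PDF1.2B, at least 40.1-fold higher. Of 20 salicylate and pathogen defence genes 15 rose and 0 fell (median 1.89, percentile 100; 1.76 with members seen on 1 array at their bound). PR2, a glucanase gene, was 38.7-fold higher and PR1 at least 22.9-fold higher. Of 65 WRKY genes 21 rose and 1 fell (median 0.41, percentile 100), WRKY62 by 20.4-fold. The ethylene list stood apart above (median 0.41, percentile 99.96) with 3 of 16 risen, among them ERF1 (2.397-fold) and ACS2 (at least 2.31-fold), both below 2-fold with normexp at 0.83 and 0.29 log2 units.

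Anthocyanin and flavonoid genes had 12 of 20 risen and 2 fallen (median 1.115, percentile 100). LDOX rose 6.19-fold beside CHS, while the flavonol regulators MYB12 and MYB111 were at least 2.12-fold and at least 2.29-fold lower; with normexp their differences were 0.12 and 0.08 log2 units. Of 26 leaf senescence genes, 10 rose and 1 fell (median 0.81, percentile 100). SAG13 rose 14.2-fold and SAG29 11.3-fold, and the 1 that fell was SAG12. Of 53 glutathione transferase genes 11 rose and 4 fell (median 0.16, percentile 99.95). GSTU11 was at least 21.0-fold higher, GSTU3 at least 3.04-fold higher and ATGSTF13 at least 9.22-fold lower, the last pair below 2-fold with normexp at 0.51 and -0.62 log2 units.

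Of the nitrogen lists, assimilation and nitrate transport lay within the random range in leaves. In leaves 0 of 17 nitrate and ammonium assimilation genes passed 2-fold (median -0.02, percentile 76.9), and the nitrate reductase genes NIA1 and NIA2 differed by 0.80 and 0.27 log2 units. Of 19 nitrate transport genes 2 rose and 1 fell (median -0.22, percentile 13.5). NRT3.1, the partner of NRT2-type transporters, rose 3.32-fold and the vacuolar exchanger gene CLC-A 2.52-fold, while NRT1.11 was 3.82-fold lower. NRT1.8, NRT2.1 and NRT2.5 differed by 0.85, -0.16 and -0.60 log2 units. Of 13 ammonium, urea and amino acid transporters 3 rose and 1 fell (median 0.36, percentile 99.89), with LHT1 2.45-fold higher, AAP3 2.7-fold higher (0.71 log2 units with normexp) and AMT1.2 2.57-fold lower. Nitrate-responsive genes stood apart above with 1 risen and 1 fallen of 18 (median 0.21, percentile 99.21), but not with the mean of all probes, at percentile 95.1. HHO3 was 2.52-fold higher and LBD39 2.03-fold lower, and both were below 2-fold with normexp at 0.9997 and -0.23 log2 units. LBD39 was also below 2-fold in the authors' table, at -0.99 log2 units.

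Cytokinin genes stood apart below in leaves, with 5 of 11 fallen and 1 risen (median -0.76, percentile 0). ARR15, a response regulator gene, was 4.06-fold lower, IPT5, a cytokinin synthesis gene, at least 3.25-fold lower and CKX4, a degradation gene, 2.23-fold higher, all below 2-fold with normexp at -0.48, -0.14 and 0.52 log2 units. CKX4 was also below 2-fold with quantile normalization, at 0.99 log2 units. Photosynthesis genes stood apart below by a small shift, with 2 of 47 fallen (median -0.30, percentile 0.03). These were LHCB1.1 (2.27-fold lower) and LHCB2.2 (2.09-fold lower), which were below 2-fold with quantile normalization, at -0.94 and -0.80 log2 units. LHCB1.1 was at -0.25 log2 units in the authors' table, and LHCB2.2 at -0.98 with loess and -0.71 over the mean of all probes. The iron deficiency list had 2 of 13 risen and 2 fallen (median -0.35, percentile 3.57): OPT3 rose 2.203-fold, ABCG37 was at least 2.603-fold higher, the iron uptake transporter gene IRT1 at least 10.3-fold lower and NAS1 2.54-fold lower. With normexp ABCG37 and IRT1 were at 0.47 and -0.77 log2 units. The list stood apart below with normexp (percentile 1.86) and with the mean of all probes (percentile 1.98). Xylem and secondary wall markers stood apart below with 0 of 9 past 2-fold (median -0.48, percentile 2.45). They did not with quantile normalization, loess, the authors' table or the mean of all probes, at percentiles 5.35, 5.74, 5.69 and 7.36.

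Smaller leaf lists that stood apart above were sugar transport, starch and dark-inducible genes, with 3 of 14 risen (median 0.34, percentile 99.96), BAM5 by 8.87-fold and the cell wall invertase gene CWINV1 by 6.52-fold. Sulphur deficiency genes had 2 of 12 risen (median 0.24, percentile 99.3) and heat shock genes 1 risen and 1 fallen of 9 (median 0.51, percentile 98.5), and in the authors' table neither list stood apart, at percentiles 89.5 and 91.97. Cytosolic ribosomal protein genes stood apart above at percentile 99.95 with a median of 0.01, with 1 of 204 risen. The other lists lay within the range of random lists on the main scale. Potassium transport had 2 risen and 2 fallen of 32 (percentile 22.4), with CIPK9, a kinase gene, 2.85-fold higher and SKOR at 0.16 log2 units, and HAK5 was not well above background. Phosphate starvation had 4 of 21 risen (percentile 4.11), RNS1 and PHO1-H1 (3.41-fold) among them. Oxidative stress had 4 of 14 (percentile 96.9), with ZAT10 and ZAT12 8.11-fold and 8.10-fold higher, and in the authors' table that list stood apart with a median of 1.47 at percentile 100, as it did over the mean of all probes at percentile 98.9. Phosphate starvation stood apart below with quantile normalization, at percentile 0.75.

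Peroxidases had 10 risen and 3 fallen of 48 in leaves (percentile 72.7), cytochromes P450 21 and 11 of 167 (percentile 80.9), aquaporins 3 and 1 of 30 (percentile 13.5) and expansins 3 and 3 of 23 (percentile 5.06). Examples were the peroxidase gene AT5G64120 (13.1-fold higher), CYP82G1 (19.8-fold higher), EXLA1 (4.99-fold higher) and EXPA8 (3.01-fold lower). Abscisic acid and dehydration had 3 risen of 27 (percentile 91.1), low oxygen 1 of 11 (percentile 61.1), flowering 1 of 7 (percentile 96.7) and Casparian strip and suberin 1 risen and 1 fallen of 11 (percentile 58.9). Chlorophyll synthesis had 1 fallen of 13 (percentile 2.89) and the circadian clock 3 of 20 (percentile 5.45). Autophagy (22 genes, percentile 95.2), cell division (10, percentile 41.6), guard cell (7, percentile 31.9), root hair (3, percentile 43.1) and reference genes (12, percentile 88.05) had 0 past 2-fold. Under some alternatives lists of this paragraph stood apart: flowering above with normexp, quantile normalization and loess (percentiles 99.2, 97.6 and 97.9), abscisic acid above with quantile normalization and the mean of all probes (97.51 and 99.8), chlorophyll synthesis below with quantile normalization and without a filter on dim probes (2.33 and 1.06), and expansins below without that filter (1.41). The glucosinolate list held 2 genes, too few for a median, of which BZO1 was 4.27-fold higher in leaves, but at 0.81 log2 units with normexp.

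Across leaf genes the median difference was -0.08 log2 units and 89.55% were below 2-fold. Of the rises 406, and of the falls 315, rest on a signal above background on 1 array only; counted at their bounds, 1261 genes rose and 631 fell. With normexp correction 566 genes rose and 135 fell, and with a 3-fold threshold 794 rose and 277 fell.

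**Figure D1:**
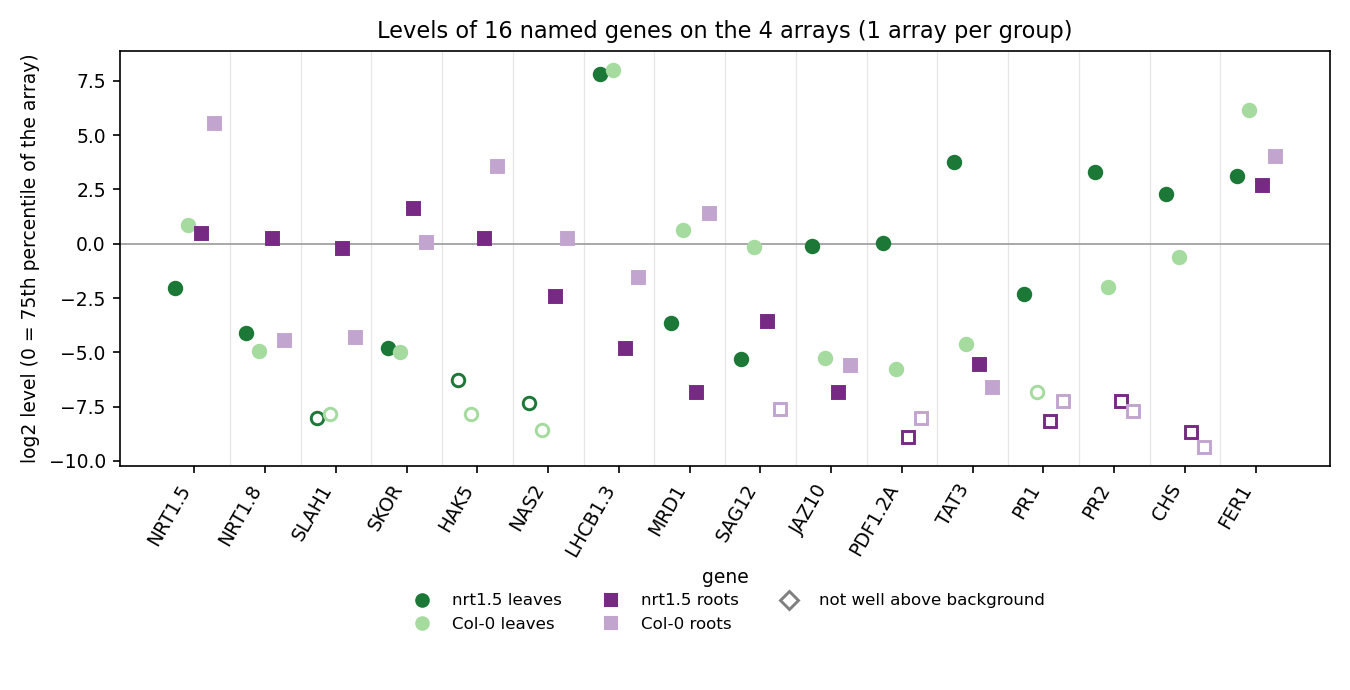
Levels of 16 named genes (x axis) as log2 of the processed signal relative to the array's 75th percentile (y axis), with 1 point per array, circles for leaves, squares for roots, dark for nrt1.5, light for Col-0, and open where the signal was not well above background. NRT1.5 lies lower in nrt1.5 in both organs, NRT1.8 rises 25.7-fold in roots, and levels of different genes come from different probes and are not compared.

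The root comparison asks the same of the organ in which the transporter loads the xylem. NRT1.8 (AT4G21680), which takes nitrate out of the xylem, was 25.7-fold higher in nrt1.5 roots, and SLAH1 (AT1G62280), linked to chloride loading of the xylem, 17.2-fold higher. SKOR (AT3G02850), the channel that releases potassium into the xylem, was 2.94-fold higher, while HAK5 (AT4G13420), a high-affinity potassium uptake transporter, was 9.84-fold lower. Of 45 photosynthesis genes 18 fell, LHCB1.3 (AT1G29930) by 9.88-fold, and several cell wall genes known from pollen rose, such as VGD1 (AT2G47040) at 27.9-fold. Of 21808 genes measured in roots, 756 rose and 429 fell.

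The largest rise in roots was AT3G51325, a RING/U-box domain gene, at 270-fold. Other rises were RALFL8 (22.8-fold), which encodes a small signalling peptide, a pectate lyase gene (AT3G01270, 19.0-fold), a pectinesterase gene (AT3G05610, 14.9-fold), AT5G26130, of the SCP-like proteins (12.4-fold), an invertase and pectin methylesterase inhibitor gene (AT1G10770, 7.90-fold) and AT5G45880, with a pollen Ole e I domain (6.09-fold). The uncharacterized genes AT3G49540 and AT3G28750 rose 13.9-fold and 10.7-fold. PGA4, a polygalacturonase gene, was at least 48.3-fold higher, AT3G01240 at least 35.6-fold, AT5G50030 at least 26.1-fold and AT5G39880 at least 24.7-fold. Of a separate set of 23 pollen genes, chosen after this pattern was seen and before their own values were, 8 rose and 0 fell among 15 measured (median 1.61, percentile 100). Of the 8, 7 were well above background in nrt1.5 roots only; counted at their bounds 5 markers rose and the median was 0.81, and with normexp 0 of the 8 stayed past 2-fold.

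The largest fall in roots was MRD1 at 306-fold lower, followed by NRT1.5 among genes well above background on both arrays. AT3G56210, an armadillo repeat gene, was 17.2-fold lower, but its other probes ranged from -6.94 to 0.03 log2 units. AT5G08250, a cytochrome P450 gene, was 13.0-fold lower, NAS2, a nicotianamine synthase gene, 6.40-fold, the lipid transfer protein gene DIR1 5.07-fold and AT1G16510, a SAUR-like gene, 4.89-fold. MRU1 was at least 21.4-fold lower, AT5G60560 at least 21.1-fold, GGPS2, a geranylgeranyl pyrophosphate synthase gene, at least 17.42-fold and AT5G03090 at least 9.54-fold. AT5G03090 was at -0.55 log2 units with normexp.

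Of 21 nitrate transport genes 4 rose and 1 fell in roots (median 0.22, percentile 99.74). NRT1.6 was the 1 that fell, 2.27-fold, with a value of 0.06 log2 units under normexp. The high-affinity transporter genes NRT2.1, NRT2.4 and NRT2.5 differed by 0.67, 0.36 and -0.19 log2 units. Of 18 assimilation genes 1 rose and 0 fell (median -0.13, percentile 28.9): ASN1, an asparagine synthetase gene, was 3.58-fold higher, and NIA1 and NIA2 differed by 0.49 and 0.08 log2 units. Nitrate-responsive genes stood apart above with 2 risen and 1 fallen of 19 (median 0.20, percentile 99.84), though not with normexp, at percentile 92.98. BT1 and BT2 were 2.54-fold and 2.297-fold higher but 0.73 and 0.80 log2 units over all their probes, and ANR1 was 2.08-fold lower but -0.94 log2 units with normexp. ANR1 was also below 2-fold in the authors' table and over all its probes, at -0.99 and -0.92 log2 units. Of 35 potassium transport genes 1 rose and 2 fell (percentile 82.7): SKOR, HAK5 and CIPK9, 3.88-fold lower but -0.94 log2 units with normexp. The 14 ammonium, urea and amino acid transporters had 0 past 2-fold (percentile 95.04), and stood apart above with the filter on both arrays, at percentile 98.3.

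Photosynthesis genes, which also mark green shoot tissue, had 18 of 45 fallen and 0 risen in roots (median -0.89, percentile 0; -0.82 with bounds; -0.27 with normexp, still apart). LHCB1.5 was 6.41-fold lower, CAB3 5.73-fold and LHCB2.2 8.74-fold, although a second LHCB2.2 probe differed by -0.45 log2 units. Chlorophyll synthesis had 2 fallen of 13 (percentile 19.8): PORB was 2.43-fold lower and GUN4 at least 1.91-fold lower, at -0.71 and -0.03 log2 units with normexp. Over all its probes PORB was at -0.67 log2 units. Cytokinin genes stood apart below as in leaves, with 2 of 13 fallen (median -0.53, percentile 0), ARR16 by 2.75-fold and ARR15 by 2.29-fold; these were at -0.12 and -0.16 log2 units with normexp. Heat shock genes stood apart below with 1 risen and 2 fallen of 8 (median -0.66, percentile 0.03; -0.48 with bounds). HSP17.4 was 2.55-fold lower, HSP70 2.08-fold lower and HSP17.6II 2.08-fold higher, at -0.20, -0.66 and 0.13 log2 units with normexp. HSP17.6II was also below 2-fold with quantile normalization, median centring, loess and in the authors' table, at 0.95 to 0.975 log2 units. Low oxygen genes stood apart below with 3 of 12 fallen (median -0.49, percentile 0), the oxidase genes PCO2 and PCO1 by 3.75-fold and 2.4-fold, but at percentile 6.34 the list was within the random range with normexp.

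Iron deficiency genes stood apart above in roots with 4 risen and 1 fallen of 19 (median 0.50, percentile 100). The transcription factor genes BHLH100 (at least 1.46-fold higher) and BHLH101 (2.51-fold higher) were at 0.37 log2 units each with normexp, another BHLH101 probe was at -0.74, and the 1 fallen gene was NAS2. The salicylate and defence list stood apart above with 2 of 17 risen (median 0.57, percentile 100; 0.37 with bounds). ALD1 was 5.70-fold higher and CYP71A13 4.04-fold, at 0.87 and 0.41 log2 units with normexp. Sulphur deficiency genes stood apart above with 1 of 14 risen (median 0.36, percentile 99.94), APR3, an adenylylsulphate reductase gene, by 2.7-fold. Of 188 cytochrome P450 genes 8 rose and 9 fell (median 0.10, percentile 100). Cytosolic ribosomal protein genes stood apart below with 1 risen and 0 fallen of 207 (median -0.23, percentile 0).

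The remaining root lists that stood apart lost this under at least 1 alternative. Root hair markers had 2 of 9 risen (median 0.45, percentile 99.95, but 93.4 with normexp), LRX1 by 2.304-fold and PRP3 by 2.02-fold, at 0.93 and 0.86 log2 units with normexp. PRP3 was also below 2-fold with median centring and over all its probes, at 0.94 and 0.76 log2 units. WRKY genes had 5 risen and 1 fallen of 68 (median 0.11, percentile 99.91; percentile 96.8 in the authors' table), WRKY40 by 4.33-fold and WRKY38 by 3.51-fold. Sugar transport and starch genes had 1 of 14 risen (median 0.26, percentile 99.36, but 91.9 in the authors' table and 92.71 without a filter on dim probes). Autophagy had 0 of 22 past 2-fold (median 0.12, percentile 99.04; percentile 97.1 over all probes). Peroxidases had 7 risen and 1 fallen of 71 (median 0.03, percentile 98.04, but 85.0 with normexp). With quantile normalization, loess, the authors' table and the mean of all probes they were at percentiles 96.86, 96.93, 92.16 and 97.48. Glutathione transferases stood apart below with 2 of 57 fallen (median -0.18, percentile 1.49, but 9.51 with normexp and 2.57 over all probes).

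Within the random range in roots on the main scale lay the jasmonate list, with 2 risen and 3 fallen of 24 (percentile 86.2), of which AOC3 was 2.12-fold higher, and the senescence list, with 3 risen and 1 fallen of 25 (percentile 22.9). SAG12 was at least 11.9-fold higher in roots and SAG29 at least 3.28-fold lower, at 0.90 and -0.07 log2 units with normexp. Ethylene had 2 of 17 risen (percentile 96.8), oxidative stress 2 of 14 (percentile 76.4), with FSD1 2.41-fold and ZAT10 2.24-fold higher, and phosphate starvation 1 risen and 2 fallen of 24 (percentile 92.3). SPX3 was 4.49-fold lower, at -0.61 log2 units with normexp. In the authors' table the oxidative stress list stood apart with a median of 0.76 at percentile 100. The ethylene list stood apart above with normexp, loess and in the authors' table, at percentiles 99.83, 97.88 and 98.1. Abscisic acid had 1 risen and 4 fallen of 27 (percentile 11.8), and RAB18 was 2.80-fold lower on its main probe but 0.86 to 1.25 log2 units higher on the others. Anthocyanin had 2 fallen of 14 (percentile 71.2), expansins 1 risen and 3 fallen of 25 (percentile 7.21), with EXPB3 2.88-fold lower, the circadian clock 1 fallen of 19 (percentile 65.3), flowering 1 fallen of 6 (percentile 6.16) and guard cell markers 1 risen of 3 (percentile 75.5). Aquaporins (34 genes, percentile 83.2), Casparian strip and suberin (13, percentile 44.5), cell division (12, percentile 30.3), xylem markers (9, percentile 85.4) and reference genes (12, percentile 66.3) had 0 past 2-fold. Expansins stood apart below in the authors' table and without a filter on dim probes (percentiles 1.46 and 1.78), as did flowering without that filter (0.94).

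Across root genes the median difference was -0.06 log2 units and 94.57% were below 2-fold; 320 rises and 228 falls rest on 1 array, and at their bounds 644 genes rose and 293 fell. After the main scaling the 7 spike-in controls had a median difference of 0.60 log2 units in roots and -0.02 in leaves, and scaling roots to them gave 379 rises and 3528 falls, so every root direction here is relative to the 75th percentile of the array. With normexp 391 genes rose and 70 fell, of which 243 and 57 had also risen or fallen on the main scale.

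**Figure D2:**
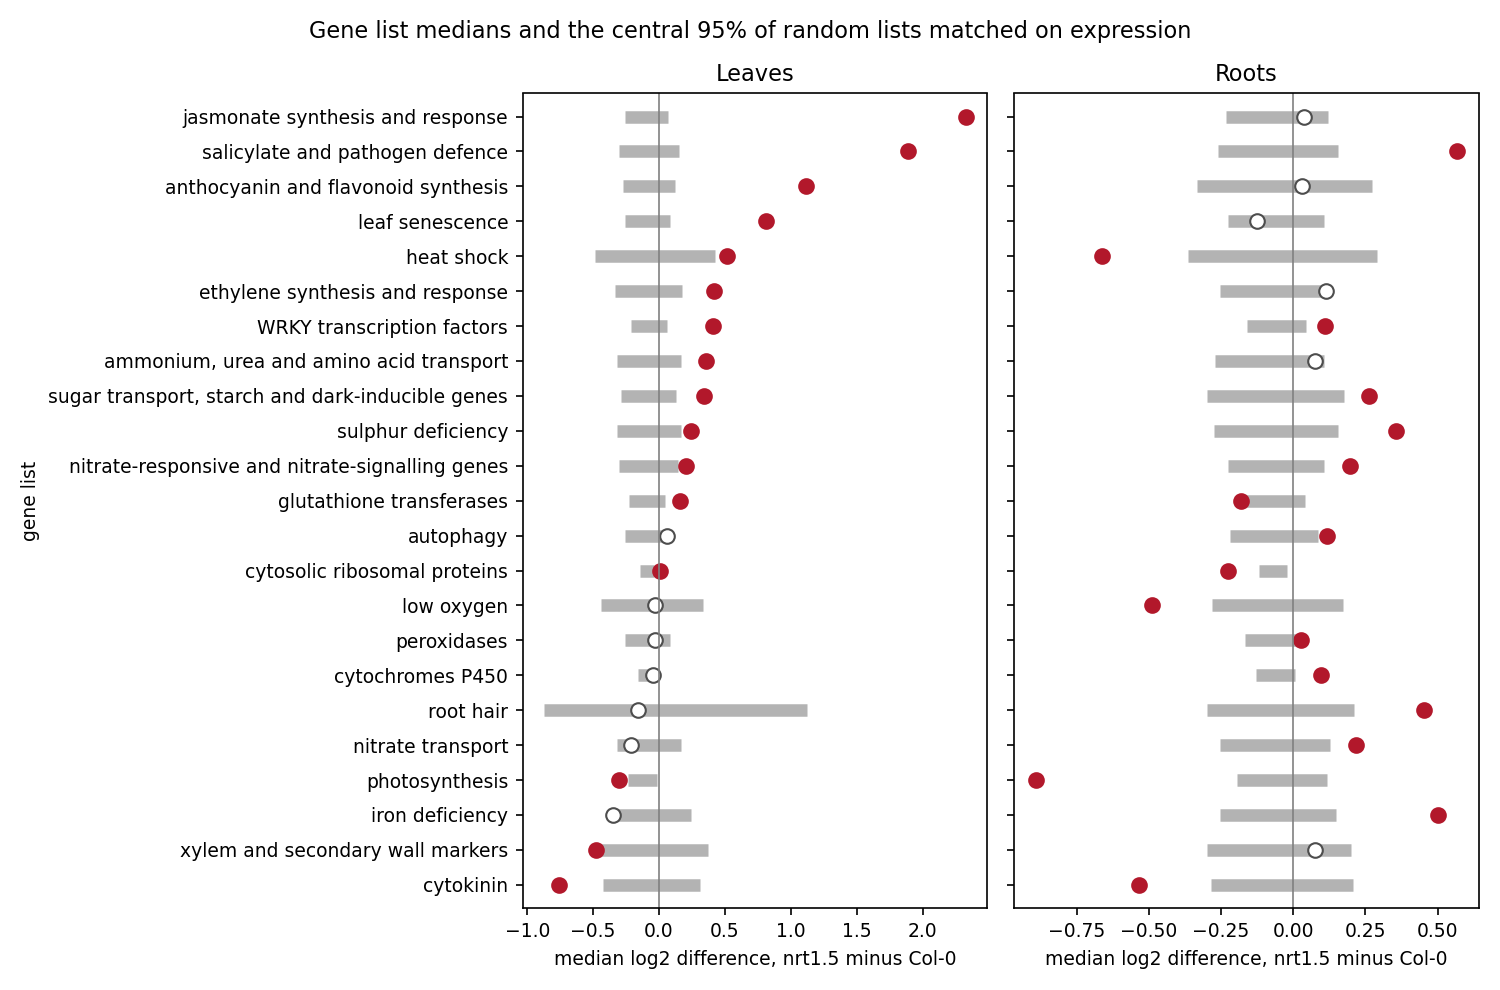
Median log2 difference, nrt1.5 minus Col-0 (x axis), of each gene list that stood apart in at least 1 organ (y axis), leaves on the left and roots on the right with their own x scales. Points are list medians, filled where the list stood apart, and grey bars give the range of medians of 10000 random lists outside which a list stands apart; the jasmonate list lies at 2.33 in leaves and 0.04 in roots, photosynthesis at -0.30 and -0.89.

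Comparing the organs asks whether the genotype difference looks alike in leaves and roots. Genes that rose in both included AT3G51325 (45.9-fold in leaves, 270-fold in roots), PGA4 (at least 15.8-fold and at least 48.3-fold), AT3G01240 (at least 8.36-fold and at least 35.6-fold) and AT5G39880 (at least 4.38-fold and at least 24.7-fold). In leaves AT3G01240 and AT5G39880 were at 0.89 and 0.49 log2 units with normexp. MRD1 fell in both, 19.6-fold in leaves and 306-fold in roots. SAG12 was 35.3-fold lower in leaves and at least 11.9-fold higher in roots, below 2-fold there with normexp at 0.90 log2 units. GGPS2 was at least 2.64-fold higher in leaves and at least 17.42-fold lower in roots, with a leaf value of 0.32 log2 units under normexp. Over all probes of GGPS2 the leaf value was 0.59 log2 units.

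Other genes, ENDO2 and JAZ10, passed 2-fold in opposite directions, and DXPS1 was counted with them although its bound in roots is below 2-fold; each was close to 0 in roots with normexp. ENDO2 was at least 119.9-fold higher in leaves and at least 2.15-fold lower in roots (0.02 log2 units with normexp). JAZ10, a repressor of jasmonate signalling, was 35.2-fold higher in leaves and 2.36-fold lower in roots (0.05, and -0.9951 over all its probes), and DXPS1 was at least 26.1-fold higher in leaves and at least 1.48-fold lower in roots (0.06). Over 19658 genes measured in both organs, 120 rose in both, where independent lists would share 28.0, and 54 fell in both, where 9.14 would be shared. Another 40 rose in leaves and fell in roots (16.8 for independent lists) and 23 the reverse (15.3). Every class exceeded its count for independent lists, so part of the excess does not depend on direction and is no sign of a shared effect. With the filter on both arrays 41 rose in both, 30 fell in both and 28 went opposite ways. Across the 19658 genes, which are not independent replicates, the differences in leaves and roots correlated with Pearson's r of 0.26 and Spearman's rho of 0.36. With normexp 19 genes rose in both, 10 fell in both and 3 went opposite ways, and with scaling to the spike-in controls, chosen after the data were seen, the counts were 76, 213 and 195.

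**Figure D3:**
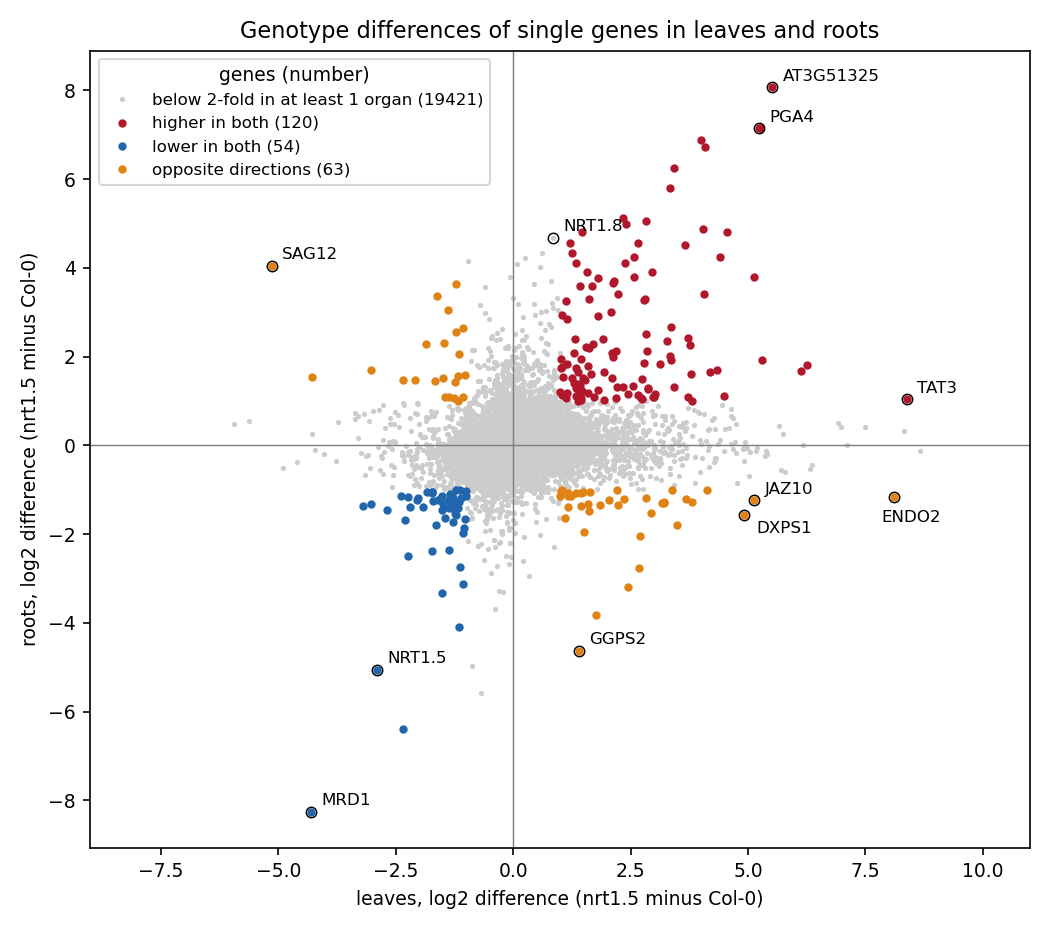
Each point is 1 of 19658 genes, with its log2 difference (nrt1.5 minus Col-0) in leaves on the x axis and in roots on the y axis, coloured by whether it passed 2-fold in both organs. The 120 red genes rose in both and the 54 blue genes fell in both, and circled genes are named in the text.

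Set against each other within a genotype, roots and leaves differed at many more genes than the genotypes did. In nrt1.5, 6607 genes were at least 2-fold higher in roots and 4558 in leaves (6334 and 4472 at their bounds), and in Col-0 the counts were 6737 and 4604 (6450 and 4464 at their bounds). All 47 photosynthesis genes were lower in roots, with medians of -10.7 log2 units in nrt1.5 and -10.1 in Col-0. All 9 root hair markers measured were higher in roots, by medians of at least 7.38 and 7.19 in nrt1.5 and Col-0, since 6 of them were not well above background in leaves. All 13 Casparian strip and suberin genes were higher in roots as well (medians of at least 7.47 and 7.59), as were all 9 xylem markers (3.61 and 2.75). Of the guard cell markers, 2 of 5 in nrt1.5 and 4 of 7 in Col-0 were well above background in leaves only; at their bounds 4 of 5 and 5 of 7 were 2-fold lower in roots (medians -3.24 and -2.70). The reference genes had medians of 0.21 and 0.22. Organ and slide cannot be told apart here.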

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

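The scaling test of the photosynthesis genes was chosen after its result was seen. The marker genes for pollen and flowers were listed after pollen genes had been noticed but before the markers' own values were looked at. The other tests in this part were set before the results they measure. The limits for the leaf genes did not fix which array would choose them, so they cover both sets of leaf genes given below.

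Genes known from pollen were among the largest rises in nrt1.5 roots and some rose in leaves as well. Of 23 separate pollen markers 34.78% were at least 2-fold higher in nrt1.5 roots and 13.04% in leaves (21.74% and 8.70% at their bounds). The root value lies between the limits set for and against pollen RNA in both nrt1.5 samples, so the number of markers cannot settle it. The markers did not move alike in roots, where VGDH1 was higher by at least 3.34 log2 units and AGP6 by 1.61 while PRF4 differed by -0.94; these were chosen after their values were seen. Of the 23, 14 were well above background in nrt1.5 roots and 8 in Col-0 roots, while of 7 flower markers 0 rose in either organ and 3 fell in roots (2 at their bounds). Of the 8 risen markers all stayed past 2-fold under 4 of the scalings but 0% did with normexp. There their median went from 2.46 log2 units (range 1.61 to 5.12) to 0.46 (0.19 to 0.92). These markers were dim in nrt1.5 roots, with log2 levels from -6.43 (CSLD4) to -2.32 (AGP6). The normexp offset of 50 shrinks the differences of dim probes. Loss of these calls could thus be foreseen, so it cannot tell whether the processing made the rises. The other 4 scalings left the median at 2.29 to 2.46, which tests little. Normexp changes the input signal, the background correction and the offset together, and which of these ended the calls was not tested. VGD1, among the larger rises that set this pattern, stayed past 2-fold in roots with normexp, as the naming rule required of it. The genotype, array position and pollen shed in the growth cabinet all stay open as untested explanations.

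Photosynthesis genes were lower in nrt1.5 roots, with 18 of 45 past 2-fold. Leaf RNA in the Col-0 root sample could give this at an estimated share of 0.030% of the leaf level, the median over the list. Between the 10th and 90th percentiles of the list the share ran from -0.010% to 0.142%. The test of other leaf genes that the median share predicts to fall depended on how they were chosen. The 3 genes chosen by signal on the nrt1.5 root array, which disfavours a fall, fell by 9.39% of the predicted amount (bootstrap range -22.4% to 37.7%). Resampling 3 genes can return only their own values as the median, so this range is not an interval for the samples. The 9 genes chosen by signal on the Col-0 root array, which favours a fall, fell by a median of 1.08 of a predicted 1.59 log2 units. That is past the limit set for leaf RNA as the cause, but the choice of these genes leans the same way. The 3 genes lay below the limit set against it, but the upper end of their range did not. Neither set settles the question, and leaf RNA cannot be told apart from a change in the roots. Part of the size may depend on the processing, since the list median was -0.27 with normexp against -0.89 to -0.97 under the other scalings. The genotype stays open and untested beyond this.

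Leaf and root differences correlated across genes, although the comparisons share no array. Removing trends with the probes' GC content and signal level left 94.61% of rho, and removing a smooth surface over the spots' places left 99.67%, which argues against either as the whole cause. Within 1 Mb of the NRT1.5 probe 2 genes changed alike where 2.42 were expected, a ratio of 0.83. This shows no excess there, but with so few genes it cannot decide on DNA of another origin beside the insertion. That window held 273 of 19657 placed genes, and a longer segment was not tested. Genotype and the array's position on the slide coincide in both comparisons and cannot be told apart, so a genotype effect in both organs stays a hypothesis.

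The following differences between organs were not tested, as each organ has 1 array per genotype. ENDO2 differed by 8.11 log2 units in leaves and -1.16 in roots, SAG12 by -5.14 and 4.05, GGPS2 by 1.399 and -4.63, JAZ10 by 5.14 and -1.24, and DXPS1 by 4.91 and -1.56. Where an array was not well above background only a bound holds: at least 119.9-fold in leaves and 2.15-fold in roots for ENDO2, 11.9-fold in roots for SAG12, 2.64-fold and 17.42-fold for GGPS2, and 26.1-fold and 1.48-fold for DXPS1, the last below 2-fold. The heat shock list had medians of 0.51 in leaves and -0.66 in roots, glutathione transferases 0.16 and -0.18, and cytosolic ribosomal proteins 0.0082 and -0.23. Of 7552 probes kept out of the gene table because they match several loci or none, 272 in leaves and 230 in roots were well above background in nrt1.5 and at least 2-fold higher than in Col-0.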

How the results depend on the processing

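Scaling to the spike-in controls was chosen after the data were seen, and the other alternatives before. NRT1.5 stayed lower in nrt1.5 in both organs under every alternative run on it, from -2.41 to -3.01 in leaves and -4.998 to -6.07 in roots, and rho stayed between 0.28 and 0.39. Counts of risen and fallen genes moved by less than 1.5 times under quantile normalization, median centring, loess, the 75th percentile of detected probes, the mean of all probes and the authors' table. The authors' table covers fewer measured genes, 17471 against 20678 in leaves and 18579 against 21808 in roots. Its counts and list values therefore differ in the genes covered as well as in processing. Of 33 list results that stood apart, 21 did so on the same side under every alternative set in advance and 0 changed side. Median centring, the 75th percentile of detected probes and spike-in scaling add 1 constant per array. They could not change a list's percentile or rho, which stayed at 0.3627, so they do not test these results. Named genes were not run under the filter settings or the 3-fold threshold. Of 137 called leaf values of named genes 69 kept their call under every alternative run on them, as did 43 of 101 root values. Normexp ended 65 of the leaf calls and 52 of the root calls. The rule's largest rises and falls had to pass 2-fold under normexp, quantile, median and loess scaling. The counts therefore overstate how often calls last. Of all main calls, normexp kept 566 of 1356 rises and 133 of 805 falls in leaves, and 243 of 756 and 57 of 429 in roots.

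With normexp 566 leaf genes rose and 135 fell, 391 root genes rose and 70 fell, 19 rose in both organs, 10 fell in both and 3 went opposite ways; of the calls 80.74% in leaves and 84.82% in roots were rises, against 62.75% and 63.8%. Normexp changes the input signal, the background correction and the offset together. Its offset of 50 is large against median processed signals of 69.5 to 107.67 per array, so it shrinks the differences of dim probes. The median difference of all measured genes was 0.03 log2 units in leaves and 0.01 in roots with normexp. How much each change contributes was not tested. Without a filter on dim probes 1174 root genes rose and 743 fell, 245 rose in both, 102 fell in both and 159 went opposite ways. Without it more genes are counted. With the filter on both arrays, which counts fewer genes, 490 leaf genes fell, 436 root genes rose and 201 fell, and 41 rose in both, 30 fell in both and 28 went opposite ways. At 3-fold 794 leaf genes rose and 277 fell, 384 root genes rose and 137 fell, and 56, 7 and 9 genes rose in both, fell in both or went opposite ways, a stricter limit by construction; rises were 74.14% and 73.7% of calls. With spike-in scaling 379 root genes rose and 3528 fell, 76 rose in both, 213 fell in both and 195 went opposite ways, because the root median of all genes shifted to -0.66 (9.70% of calls were rises). Median centring shifted the leaf median from -0.08 to -0.20.

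With normexp 232 of the main calls in leaves and 180 in roots had the opposite sign. Among named genes these falls of the main scale turned to small positive log2 differences in leaves: CASP1 0.1032, MYB12 0.1168, MYB111 0.077, BETA-TIP 0.1448, GSTU28 0.0583, HSP23.6 0.0493, AT2G35380 0.1175, CHX21 0.0847, AT5G26130 0.1742 and AT5G60560 0.0598. In roots they were ENDO2 0.02, AT1G76800 0.0005, AT3G32090 0.0508, UGT75C1 0.0183, CYP79A3P 0.0536, AP1 0.1003, JAZ10 0.0531, NRT1.6 0.062 and DXPS1 0.0594. RAB18 in roots turned to 0.1799 over the mean of its probes, which disagree. The values of the other named genes were small with normexp, whose offset shrinks the differences of dim probes, so their sign alone gives no direction. How much the offset contributes was not tested. Leaving out replicates and a slide block could not be run with 1 array per group, and leaving out saturated probes changes nothing, since there were 0. No plant is numbered, so plants could not be paired; pairing the genotypes by organ would assume a shared effect and was not run. Signal over background limits many calls: 721 leaf and 548 root calls rest on 1 array.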

Other observations

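The gene families in this part were taken from shared symbol stems with at least 6 measured members and were chosen after the data were seen; 321 families were scanned in leaves, where 48 stood apart from random lists by the same percentiles, and 341 in roots, where 58 did. Their members' probes were not checked for cross-hybridisation.

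In nrt1.5 leaves 11 of 16 SAUR genes, which respond early to auxin, fell and 2 rose (median -1.28, percentile 0; -0.57 with normexp, where 4 fell and 1 rose). SAUR26 was 3.41-fold lower, SAUR63 2.84-fold and SAUR24 2.76-fold, while SAUR36 was 3.04-fold higher. Of 48 receptor-like protein (RLP) genes 20 rose and 2 fell (median 0.59, percentile 100; 0.34 with normexp, where 10 rose), RLP40 by 36.9-fold and RLP23 by 11.1-fold. Of 7 calmodulin-like CML genes 4 rose (median 1.16, percentile 99.96; 0.65 with normexp, where 3 rose), CML37 by 8.75-fold beside CML41. Among 9 methionine sulphoxide reductase genes of the MSRB type 4 rose (median 0.80, percentile 99.99; 0.71 with normexp, where 2 rose), MSRB8 by 19.7-fold and MSRB9 by 19.3-fold. The medians of the CML and MSRB families stayed above 0 under all 5 scalings.

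The BBX family of zinc finger transcription factors had lower medians in both organs. In leaves 5 of 16 fell and 1 rose (median -0.58, percentile 0; -0.28 with normexp, where 3 fell and 0 rose), BBX30 by 4.92-fold and BBX16 by 3.55-fold, with BBX32 3.36-fold higher. In roots 5 of 15 fell (median -0.43, percentile 0.44), BBX28 by 2.33-fold, although with normexp the root median was 0.01. In roots 3 of 6 UPL ubiquitin ligase genes rose (median 0.66, percentile 99.98; 0.98 with normexp), UPL4 by 3.24-fold and UPL7 by 3.00-fold, and 11 mitochondrial SDH genes had a median of -0.46 (percentile 0; -0.33 with normexp) with 0 past 2-fold.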
